A study of Zea mays with 16 samples.

How the data were processed

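Endosperm was dissected from maize kernels 16 to 18 days after pollination in the W22 inbred background, per the labels' protocols. Kernels homozygous for 1 of 2 alleles of rbm48, umu1 or umu2, were set against normal sibling kernels. Each of the 4 groups (umu1 mutant, umu1 normal, umu2 mutant and umu2 normal) had 4 libraries, 16 in all. Total RNA went into TruSeq libraries that do not keep strand, with a median insert of 200 bases, and was sequenced as pairs of 100-base reads, per the labels. The umu1 libraries carry the label of lane 2 and the umu2 libraries that of lane 3, so allele and lane cannot be told apart. Comparisons of mutant with normal lie within 1 lane.

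The authors deposited 3 count files per library and 1 comparison table per allele. The first file holds whole-number read counts for 63293 transcript models, with the 5 summary lines that HTSeq-count writes. The other 2 hold raw counts of reads inside each annotated intron and of reads spanning the junction of its flanking exons, per the file names and the deposited values. An intron with no read of a kind is left out of that file and was taken as 0. The submitters' processing notes name CASAVA, cutadapt 1.1, Trimmomatic 0.22, GSNAP 2013-07-20, HTSeq, DESeq, DESeq2 and bedtools, without roles, and the build B73 RefGen_v4. The identifiers in the files are of an older style than that build, so the build of the coordinates is uncertain. The authors' deposited tables give a log2 fold change and a p-value with its adjusted p-value per model from DESeq2. The deposited counts are whole numbers with a different total in each library, that is, not scaled.

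Counting was per transcript model. A read that fits 2 or more models goes to the ambiguous line, not to any model, so the count of a model of a multi-model gene covers only the part that is its own. Of 39423 genes, 26766 have a single model and 12657 have more. Ambiguous reads made up 33.7 to 52.9% of counted reads per library and reads outside models 6.41 to 13.0%. Both stayed out of library sizes and tests. Because strand was not kept, reads of overlapping genes on opposite strands cannot be told apart. Counts of zeins and other families of near-identical copies are uncertain for single copies.

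Reads assigned to models ranged from 11.8 to 24.6 M per library. Differential expression was tested per allele with edgeR 4.0.16 in R 4.3.3: filterByExpr with its defaults, TMM scaling, and the quasi-likelihood test (glmQLFit, glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. The filter drops models low in both genotypes, so a model near 0 CPM in 1 genotype was tested only if higher in the other. Log2 fold changes are mutant over normal and are given with their standard errors (SE). Expression levels are CPM, counts scaled to library totals times the TMM factor, as mean ± SD over 4 libraries. TMM factors were 1.43 to 2.14 in mutants and 0.526 to 0.664 in normal siblings. All changes are therefore relative to the bulk of transcripts. With total counts alone the median log2 fold change of all tested models was 1.77 in umu1 and 1.49 in umu2. The allele difference was tested as an interaction term over all 16 libraries. The alleles share no library.

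Intron retention was tested per allele with edgeR's quasi-likelihood test on 2 columns per library, intron and spanning reads, with library and read kind in the model. The tested term was read kind by genotype. Introns needed a total of at least 10 reads of each kind over the 8 libraries. The intron files name 10 chromosomes, 123912 introns with intron reads and 107008 with spanning reads, of a median length of 159 bases over all 130073. Intron starts in the files count from 0. Taken so, 44.3% of 90437 exons between neighbouring introns had a length divisible by 3, against 27.8% with starts counted from 1. Coordinates are printed counted from 1. Library medians of the log2 ratio used 0.5 added to both reads. A fold against a group at 0 was bounded with a floor of 3 reads over the group. That floor covers counting error only. Intron classes, the genes that hold the introns, and reads of the minor against the major spliceosome's introns were not analysed here, since no genome sequence was used here.

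Names came from a table of the assembly Zm-B73-REFERENCE-NAM-5.0, used for names alone. It matched 18770 of the gene identifiers through older names, of which 2641 have an informative name and 520 matched 2 or more entries. No entry in it is named rbm48, so the mutated gene itself was not analysed here. The 24 gene lists were fixed before the data were examined as symbols and description words, along with the design, the tests and the rule for named genes. Each gene of a list was counted by its model with the highest mean count. Some lists hold several genes of the same name. An identifier at first mention then marks the gene meant, and its values do not stand for the others. The table holds no descriptions. The lists were therefore rebuilt as name patterns after the table, the library totals, the most abundant models and the counts of changed models had been seen, and before any single gene's result was. The 16 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, adjusted over lists. The rule for named genes took the 10 largest rises and 10 largest falls by mean log2 fold change among named models past the threshold in both alleles, with groups fully apart and an average log2 CPM of at least 1. It also took up to 4 members per list by the larger adjusted p, the 4 introns most raised and most lowered in both alleles, and up to 3 models per direction of the allele difference.

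Values per library were compared by exact two-sided permutation tests, 4 libraries against 4, whose smallest possible p is 0.0286. Nothing in the labels gives separate ears or plants for every pool, so p-values measure the spread between these pools. The design text in the labels pairs each mutant pool with a normal sibling pool, so replicate numbers were taken to pair libraries. The permutation tests of library values do not keep these pairs. Splits that part every pair number 8, too few for a p under 0.05. Correlations of same-numbered libraries' deviations from group means were 0.325, 0.206, 0.149 and 0.232 in umu1 and 0.046, −0.053, 0.189 and 0.100 in umu2. Fits with a replicate block were run as alternatives. Other alternatives were RLE scaling, total counts alone, no low-count filter, DESeq2 1.42.0, all 16 libraries in one fit, a 2-fold limit, other read minimums, intron reads alone, and leaving out each library. Chosen after the data were seen were counts summed per gene, single-model genes, leaving out zeins, centring intron ratios per library, and leaving out umu1 mutant 2, which stood apart in reads spanning junctions, and umu2 mutant 2, which had the highest share of reads outside models. Whether the spanning reads of umu1 mutant 2 (19.0 M against 8.66 to 9.64 M in the other umu1 mutants) were counted in the same way is uncertain. Up to 100 other splits of the libraries were tested per count, and 34 others per allele for introns without those 2 libraries. The comparison of raised introns with their neighbours was chosen after the data were seen.

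The tests were tested on simulated counts drawn from the real means and library sizes, with 200 changed features. Within each allele far more models and introns were called in the data, so the rates below hold for the simulated counts alone. The umu1 test recovered 32% of 2-fold and 76% of 4-fold changes, with 5 false calls among 14614 models. The umu2 test recovered 25% and 81%, with 4 false calls among 13291. The allele difference recovered 10% and 39%, with 2 false calls among 16019. The intron test recovered 24% of 4-fold and 81% of 16-fold changes in umu1, with 10 false calls among 66375 introns, and 33% and 91% in umu2, with 8 among 64026. Simulated intron and spanning reads had a preset spread, not that of the data, so these rates do not carry over to the real introns. A raised list was called and an unchanged list was not, in both alleles. Genes of these lists were drawn independently, whereas estimated correlations of real lists reached 0.792, so this does not test correlated lists. Tables and plots used numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.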

Results

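RNA was measured in developing maize endosperm of 2 rbm48 mutant alleles, umu1 and umu2, each against normal sibling kernels, with 4 libraries per group. RBM48 is an RNA-binding protein that acts with the minor spliceosome, which removes a small class of introns. Reads assigned to transcript models numbered 14.2, 14.8, 11.8 and 13.3 M in the umu1 mutants and 19.3, 17.2, 20.6 and 17.1 M in their normal siblings. The umu2 mutants had 15.1, 14.0, 16.2 and 16.5 M and their normal siblings 20.3, 24.6, 15.2 and 19.8 M. The comparisons asked which transcripts and which introns differed between mutant and normal endosperm, and whether the alleles differed. Reads inside introns and reads spanning exon junctions were counted in the same libraries.

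Zein transcripts, which encode the storage proteins of maize endosperm, took a smaller share of the mutant libraries. They held 15.6% ± 5.37 of assigned reads in umu1 mutants against 47.7% ± 0.604 in normal siblings, and 24.4% ± 4.71 against 45.9% ± 2.79 in umu2 (SD, n = 4; exact two-sided permutation p = 0.0286 in each, the smallest possible). The 20 most abundant models held 24% ± 6.48 against 68.7% ± 0.655 in umu1 and 38.0% ± 7.59 against 70.1% ± 1.11 in umu2 (exact two-sided permutation p = 0.0286 in each). More models had reads in mutants: 28198 ± 501 against 21652 ± 312 in umu1 and 25860 ± 1843 against 20691 ± 1107 in umu2 (SD, n = 4; exact two-sided permutation p = 0.0286 in each). That number depends on the depth left for models other than the most abundant. Library totals times the TMM factor were 20.5 to 26.7 M in umu1 mutants against 9.79 to 11.2 M in normal siblings. In umu2 they were 21.5 to 29.7 M against 8.82 to 16.3 M. Numbers of models with reads were not compared at equal depth. Reads that fit several models made up 50.8% ± 1.43 against 37.9% ± 0.462 in umu1 and 44.5% ± 0.732 against 34.6% ± 0.627 in umu2 (exact two-sided permutation p = 0.0286 in each).

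**Figure D1:**
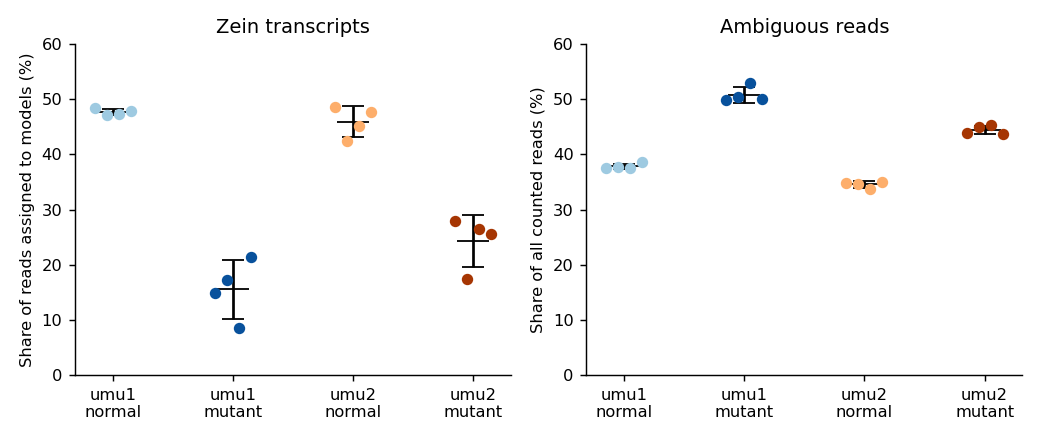
Share of assigned reads in zein transcripts (left, percent) and share of counted reads that fit several models (right, percent), with a point per library and bars for mean ± SD of 4 libraries. All mutant libraries, at most 28% zein, lay below all normal libraries, and all mutant libraries lay above the normal libraries in reads that fit several models.

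In umu1 mutants all 26 tested zeins fell, with a median log2 fold change of −2.98, while 9 of 10 tested genes of the basal transfer layer, the cells that take up nutrients from the mother plant, rose. Genes of cytosolic ribosomes (17 of 30), of DNA replication and cyclins (11 of 16) and of core histones (6 of 7) also rose. At single genes, sugary2, a starch synthase gene, fell from 1727 ± 316 to 373 ± 147 CPM, and crt2, a calreticulin gene, rose from 234.0 ± 18.5 to 638 ± 88.6 CPM (SD, n = 4). Of 15829 tested models 7841 changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 4278 higher and 3563 lower. Over all tested models, called or not, all mutant libraries lay on one side of all normal libraries in 7359, where chance gives 2.86%. At least 2-fold changes numbered 5007. With total counts alone 13943 models changed, 13808 higher and 135 lower, so most directions are relative to the bulk of transcripts. The gene sugary2 fell there too (log2 fold change −0.54).

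In umu2 mutants 24 of 25 tested zeins fell, with a median log2 fold change of −2.05, and 6 of 15 genes of starch synthesis fell. Genes of cytosolic ribosomes (16 of 29) and of DNA replication and cyclins (8 of 16) rose. The gene sugary2 fell from 1187 ± 155 to 248 ± 136 CPM, and crt2 rose from 282 ± 17.3 to 761 ± 92.8 CPM (SD, n = 4). Of 13720 tested models 4575 changed at an adjusted p under 0.05 (edgeR's quasi-likelihood test, Benjamini-Hochberg), 2493 higher and 2082 lower, and groups were fully apart in 4620 of all tested models, where chance gives 2.86%. At least 2-fold changes numbered 2774. Total counts alone gave 11366, 99% of them higher.

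Many of these changes were shared by the alleles. Among named genes with an average log2 CPM of at least 1 and groups fully apart, the largest rises common to both were those of LTP3, a lipid transfer protein gene (4.94 ± 3.07 against 0.179 ± 0.357 CPM in umu1 and 5.40 ± 3.50 against 0.0211 ± 0.0421 in umu2), bap-3a, an antifungal protein gene of the basal endosperm (log2 fold changes 5.88 ± 1.22 and 6.09 ± 1.16, SE, in umu1 and umu2), HAK5, a potassium transporter gene (5.77 ± 0.596 and 5.80 ± 0.769), and chiA, a chitinase gene (5.85 ± 0.681 and 4.97 ± 0.874). MGL3 (4.01 ± 0.652 and 3.85 ± 0.639), HK1a2 (4.16 ± 0.352 and 3.54 ± 0.428), the MYB gene MYB112 (3.47 ± 0.680 and 3.95 ± 0.618), IIG2 (4.25 ± 0.545 and 3.05 ± 0.662), PepR1 (3.62 ± 0.331 and 3.38 ± 0.384) and the dehydrin gene dhn1 (3.10 ± 0.908 and 3.25 ± 0.584) followed. The dhn1 call in umu1 was lost with DESeq2, at a log2 fold change of 3.12.

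The largest falls common to both alleles were those of NAC78, a NAC transcription factor gene (−5.42 ± 0.484 and −3.82 ± 0.626), por2, a protochlorophyllide oxidoreductase gene (−2.65 ± 0.50 and −5.34 ± 0.539), and DOF22, a Dof transcription factor gene (−2.77 ± 0.499 and −3.30 ± 0.434). The other 7 were zein models. The alpha zein z1A1_7 fell from 51510 ± 11000 to 1945 ± 1060 CPM in umu1 and from 49980 ± 6858 to 7662 ± 4748 in umu2 (SD, n = 4). Log2 fold changes were −3.48 ± 0.348 and −3.29 ± 0.488 for the delta zein dzs18, −3.74 ± 0.399 and −2.86 ± 0.363 for the gamma zein gz50, −3.70 ± 0.376 and −2.52 ± 0.406 for z1A2_1, and −3.26 ± 0.277 and −2.40 ± 0.400 for z1A1_5. A pair of models of z1A1_3 fell by 3.66 and 3.62 in umu1 and by 2.69 and 2.43 in umu2. How reads shared between zein copies at different places were counted is not known here, so a single copy's value is uncertain.

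Of 13309 models tested in both alleles, 3924 changed in the same direction and 3 in opposite directions. The 2068 raised in both exceeded the 612 expected of independent lists (Fisher's exact test, odds ratio 44.1), and the 1856 lowered in both exceeded 516 (odds ratio 61.9), with p below the smallest number the software can hold. Across these models log2 fold changes of the alleles correlated with a Pearson r of 0.868 and a Spearman rho of 0.872, and models are not independent replicates. Among the shared models the median absolute log2 fold change was 1.32 in umu1 and 1.15 in umu2, and 67.5% had the larger value in umu1. Total counts alone gave 10745 shared changes.

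**Figure D2:**
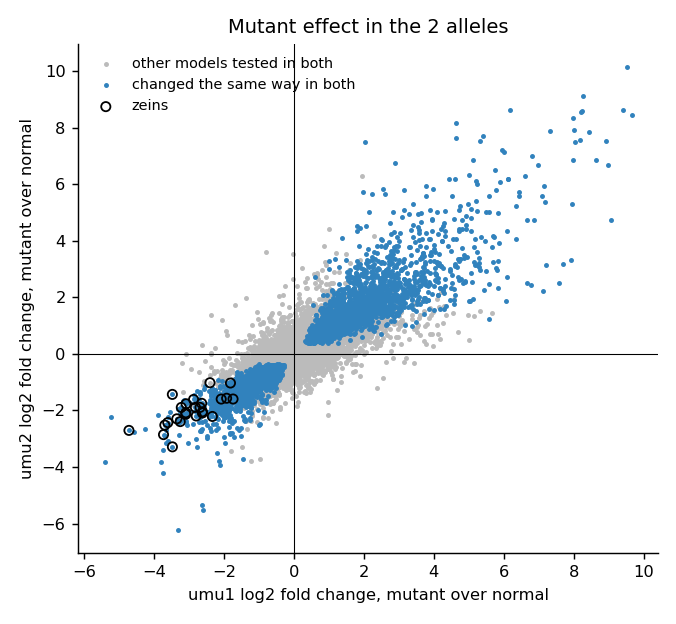
Log2 fold change of mutant over normal endosperm in umu1 (x axis) and umu2 (y axis) for each of 13309 models, with the 3924 changed the same way in both in blue and zeins circled. Zeins lie at the lower left in both alleles, where with total counts alone 23 of 25 in umu2 and all 26 in umu1 stayed below 0.

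Zein and starch synthesis genes fell as groups relative to other genes with a preset correlation, and neither set passed with an estimated one. With total counts alone zeins still fell while most called starch genes rose. Zeins fell in 26 of 26 tested genes in umu1 and 24 of 25 in umu2, each gene counted by its most abundant model (26 and 25 when adjusted over the list alone), and with total counts alone 20 and 15 fell, with 2 of the 25 umu2 values positive. The set test gave limma camera adjusted p = 2.66e-17 and 3.02e-18, with adjusted p = 0.298 and 0.361 with an estimated correlation. Among single-model genes 20 of 20 zeins fell in umu1 and 19 of 20 in umu2. Besides gz50, the list members with the lowest p were the beta zein bz15 (−2.34 ± 0.170 and −2.21 ± 0.22) and the alpha zeins z1C1_2 (−2.62 ± 0.331 and −2.05 ± 0.254) and z1C1_1 (−2.88 ± 0.330 and −1.61 ± 0.226).

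Starch synthesis had 7 falls and 1 rise among 15 tested genes in umu1 and 6 falls and no rise among 15 in umu2, the same when adjusted over the list alone, whereas with total counts alone 10 rose and 1 fell in umu1 and 7 rose and 2 fell in umu2. As a set, tested against all other genes, it pointed down with limma camera adjusted p = 0.00904 and 0.00549, 0.0107 and 0.000142 with total counts alone, and 0.298 and 0.361 with an estimated correlation. The genes with the lowest p were ss1, a starch synthase gene (−1.62 ± 0.207 and −1.89 ± 0.259), and sugary2 (−2.21 ± 0.249 and −2.26 ± 0.379), followed by the starch branching enzyme genes sbe1 (GRMZM2G088737; −1.04 ± 0.138 and −1.04 ± 0.209) and ae1 (GRMZM2G032628; −1.48 ± 0.223 and −1.13 ± 0.304). The list also holds a further sbe1 (GRMZM2G088753) and a further ae1 (GRMZM2G039942), whose values are not given here. Values of sbe1 and ae1 in both alleles and of ss1 in umu1 were positive with total counts alone. Among sugar transport and invertase genes 2 of 3 rose in umu1 and 1 of 2 in umu2, the same adjusted over the list alone. The cell wall invertase gene incw1 had 2.88 ± 0.354 and 3.37 ± 0.626. The transporter gene sut4 had 0.13 and 0.27 and did not pass.

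Regulators of endosperm genes moved both ways, with 5 falls and 3 rises among 13 in umu1 and 4 falls and no rise among 11 in umu2, the same adjusted over the list alone, whereas with total counts alone 9 rose and none fell in umu1 and 6 rose and 1 fell in umu2. The set did not pass (limma camera adjusted p = 0.443 and 0.177), but against all other genes it passed downward in umu2 with total counts alone (limma camera adjusted p = 0.0244, over a range of 0.0244 to 0.575), and in umu1 its median of −0.16 and its mean of 0.25 differ in sign. The transcription factor genes pbf1 (GRMZM2G146283; −1.59 ± 0.151 and −1.30 ± 0.203) and o2 (−1.29 ± 0.294 and −1.46 ± 0.334), which activate zein genes, fell, as did DOF36 (−1.46 ± 0.150 and −1.62 ± 0.312) and the aleurone regulator Nkd1 (−1.87 ± 0.480 and −1.88 ± 0.295). With total counts alone pbf1 was positive in both alleles and DOF36 and o2 in umu1.

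In the basal transfer layer list 9 of 10 rose and 1 fell in umu1 and 3 of 10 rose in umu2 (4 when adjusted over the list alone in umu2, unchanged in umu1). The list names 17 genes, and the others were too low to be tested. The set test gave limma camera adjusted p = 0.00388 in umu1 and 0.177 in umu2, and adjusted p = 0.496 and 0.889 with an estimated correlation. The umu2 set passed without umu2 mutant 2 (limma camera adjusted p = 0.0125, over a range of 0.0125 to 0.956). With total counts alone 10 and 9 rose, but the umu1 set no longer passed (limma camera adjusted p = 0.192) and the umu2 test pointed down (0.956). The gene betl10 had 4.49 ± 0.430 and 2.33 ± 0.719 and bap-3b 6.77 ± 0.832 and 2.43 ± 0.816, while MEG1 rose in umu1 (4.15 ± 0.383) and did not pass in umu2 (1.65 ± 0.613), where it passed with a replicate block (1.87). The betl10 call in umu2 was lost without umu2 mutant 1 (1.98) or 4 (2.02) or normal 2 (2.46) or 4 (2.05), and that of bap-3b without umu2 mutant 1 (2.02) or 4 (2.37) or normal 2 (2.71), 3 (2.07) or 4 (1.99). The allele difference did not pass for betl10, bap-3b or MEG1. Of the embryo-surrounding region genes 3 of 3 rose in umu1 and none of 2 passed in umu2 (1 when adjusted over the list alone). The gene esr-6 had 2.66 ± 0.815 and 1.68 ± 0.613, the latter passing with a replicate block (1.81). The esr-6 call in umu1 was lost without umu1 mutant 2 (2.38). That of ESR1 (GRMZM2G315601) was lost without umu1 mutant 3 (1.31) or 4 (1.32) or normal 1 (1.23) or 2 (1.19).

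Aleurone and anthocyanin genes rose in 3 of 3 tested in umu1 and 2 of 2 in umu2, the same adjusted over the list alone. The list names 11 genes, and the others were too low to be tested. A gene near 0 CPM in normal siblings was tested only if higher in mutants, so these counts do not show that the list rose. The anthocyanidin synthase gene a2 had 4.81 ± 0.938 and 4.40 ± 0.847. The flavanone hydroxylase gene f3h was at 4.55 ± 2.67 against 0.0478 ± 0.0555 CPM in umu1 and 9.49 ± 7.76 against 0.610 ± 0.440 in umu2. Embryo markers moved both ways, 2 up and 1 down of 5 in each allele, the same adjusted over the list alone (limma camera adjusted p = 0.792 and 0.735). The globulin gene glb3 fell (−1.85 ± 0.239 and −1.66 ± 0.207), and rab17, which is the dhn1 named above and also in the desiccation list, and the oleosin gene ole1 (2.29 ± 0.362 and 0.80 ± 0.272) rose. The ole1 call in umu2 was lost without umu2 mutant 1 (0.73) or 4 (0.72) or normal 1 (0.62), 3 (0.59) or 4 (0.89). Markers of green maternal tissue gave 1 tested gene in umu1, which did not pass, and none in umu2.

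Cytosolic ribosome genes rose in 17 and fell in 4 of 30 in umu1 and rose in 16 and fell in 1 of 29 in umu2 (18 and 17 rises adjusted over the list alone, falls unchanged). The set test gave limma camera adjusted p = 0.00388 and 0.00678, 0.00237 and 0.0420 with total counts alone, and adjusted p = 0.298 and 0.361 with an estimated correlation. Examples are rps13 (2.63 ± 0.412 and 2.97 ± 0.375), rpl39 (1.30 ± 0.22 and 1.18 ± 0.187) and rpp2a-4 (0.77 ± 0.165 and 0.76 ± 0.147). DNA replication and cyclin genes rose in 11 and fell in 2 of 16 in umu1 and rose in 8 of 16 in umu2 (12 rises in umu1 adjusted over the list alone, otherwise unchanged). As a set they passed with limma camera adjusted p = 0.00789 and 0.0438, and adjusted p = 0.233 and 0.361 with an estimated correlation. The umu2 call was lost with total counts alone (limma camera adjusted p = 0.116) and without umu2 mutant 1 (0.0679) or 3 (0.184) or normal 1 (0.0540), 3 (0.0771) or 4 (0.0565), a range of 0.0540 to 0.184. Examples are RNRL2, a ribonucleotide reductase gene (1.55 ± 0.126 and 1.12 ± 0.156), pcna1, the sliding clamp of DNA polymerase (2.32 ± 0.226 and 1.71 ± 0.272), and cyclin8 (2.03 ± 0.405 and 1.72 ± 0.311).

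Core histone genes rose in 6 of 7 in umu1 and 1 of 7 in umu2, the same adjusted over the list alone. As a set they had limma camera adjusted p = 0.00904 in umu1 and 0.253 in umu2, and adjusted p = 0.496 and 0.889 with an estimated correlation, and with total counts alone the umu1 call was lost (limma camera adjusted p = 0.141). The umu2 set passed without umu2 mutant 2 (limma camera adjusted p = 0.0430, over a range of 0.0430 to 0.889). The gene his2b2 had 1.20 ± 0.243 and 0.75 ± 0.213, and H4C13 (GRMZM2G084195) had 1.94 ± 0.308 and, not passing, 0.72 ± 0.293. The his2b2 call in umu2 was lost without umu2 mutant 1 (0.65) or normal 1 (0.67), 3 (0.69) or 4 (0.62).

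**Figure D3:**
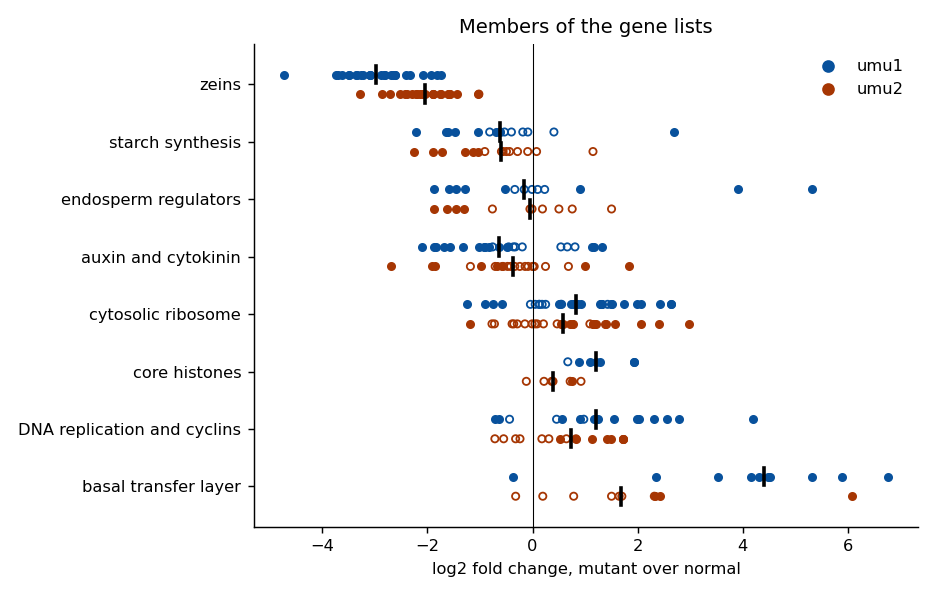
Log2 fold change of mutant over normal endosperm (x axis) for each tested member of 8 gene lists (y axis) in umu1 (blue) and umu2 (red), filled where it passed the test, with a black bar at the median. Zeins lie left of 0 and ribosome, histone, replication and transfer layer medians right of it, and the medians of starch, regulator and auxin and cytokinin genes, left of 0 here, lie right of 0 with total counts alone.

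Auxin and cytokinin genes fell in 12 and rose in 3 of 23 in umu1 and fell in 6 and rose in 2 of 22 in umu2, the same adjusted over the list alone, whereas with total counts alone 15 and 14 rose and none fell. The set test against all other genes pointed down with limma camera adjusted p = 0.0241 and 0.103, 0.00237 and 0.00259 with total counts alone, and 0.338 and 0.831 with an estimated correlation. The umu2 set also passed without umu2 mutant 2 (0.0430) or 4 (0.0299). The umu1 call was lost without umu1 normal 1 (0.0614), 2 (0.108), 3 (0.0536) or 4 (0.160), and with single-model genes (0.182), a range of 0.0536 to 0.182. The cytokinin oxidase gene cko2 (−1.88 ± 0.245 and −1.85 ± 0.316) and the auxin response factor genes ARF23 (−2.10 ± 0.221 and −1.91 ± 0.372) and ARF11 (−1.02 ± 0.271 and −0.98 ± 0.166) fell and ARF16 rose (1.18 ± 0.209 and 1.01 ± 0.245). ARF11 was positive in both alleles with total counts alone.

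Defence and stress lists held large rises at few genes. Pathogenesis-related genes rose in 4 of 4 tested in umu1 and 2 of 2 in umu2, the same adjusted over the list alone. The list names 10 genes, and the others were too low to be tested. A gene near 0 CPM in normal siblings was tested only if higher in mutants, so these counts do not show that the list rose. Besides chiA they include a chitinase gene (GRMZM2G453805) at 8.95 ± 5.70 against 0.0478 ± 0.0555 CPM in umu1 and 1.56 ± 1.42 CPM against 0 in umu2. Of mitochondrial stress genes 2 of 4 rose in umu1 and 3 of 4 in umu2, the same adjusted over the list alone. The alternative oxidase gene Aox had 3.90 ± 0.350 and 4.05 ± 0.755 and the prohibitin gene phb2 1.15 ± 0.251 and 1.53 ± 0.286. ER folding and stress genes rose in 3 and fell in 4 of 17 in umu1 and rose in 5 and fell in 5 of 15 in umu2 (6 rises in umu2 adjusted over the list alone), whereas with total counts alone 17 and 14 rose and none fell (limma camera adjusted p = 0.927 and 0.735 for the set as tested). The gene crt2 had 1.45 ± 0.134 and 1.44 ± 0.149, bip2, a chaperone of the endoplasmic reticulum, 1.05 ± 0.194 and 1.28 ± 0.263, and der2 (GRMZM2G082976) −0.83 ± 0.164 and −0.61 ± 0.153. ABA and desiccation genes rose in 6 and fell in 4 of 13 in umu1 and rose in 3 and fell in 2 of 11 in umu2 (3 falls in umu2 adjusted over the list alone), and with total counts alone 11 rose and 1 fell in umu1 and 6 rose and none fell in umu2. This set did not pass (limma camera adjusted p = 0.792 and 0.735), and its umu2 median of −0.05 and mean of 0.37 differ in sign, with the test pointing down. Its dehydrin gene dehydrin7 rose (2.62 ± 0.501 and 2.87 ± 0.433) and the ABA receptor genes PYL6 (−1.84 ± 0.222 and −1.02 ± 0.190) and PYL10 (GRMZM2G165567; −0.88 ± 0.267 and −1.07 ± 0.246) fell, though this PYL10 was positive with total counts alone in both alleles and PYL6 in umu2. A further gene named PYL10 (GRMZM2G063882) did not pass (−0.15 and −0.04).

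The other lists did not pass as sets with all libraries. Heat shock genes rose in 2 and fell in 2 of 16 in umu1 (1 rise adjusted over the list alone) and fell in 2 of 13 in umu2, whereas with total counts alone 13 and 9 rose (limma camera adjusted p = 0.708 and 0.658 as tested), with a umu1 median of 0.01 against a mean of −0.07. Their factor gene Hsf01 fell (−2.69 ± 0.491 and −1.34 ± 0.388), though it was positive in umu2 with total counts alone, and the umu2 call was lost without umu2 mutant 1 (−1.22) or 2 (−1.27). Cell wall genes rose in 5 and fell in 1 of 11 in umu1 and rose in 3 and fell in 1 of 8 in umu2 (limma camera adjusted p = 0.249 and 0.735). The expansin gene expa2 had 2.05 ± 0.271 and 2.92 ± 0.526. The cellulose synthase gene CesA-6 had −0.92 ± 0.141 and −0.79 ± 0.187, positive with total counts alone. Cell death and proteolysis genes rose in 2 and fell in 3 of 10 in umu1 and rose in 1 and fell in 1 of 9 in umu2, whereas with total counts alone 10 and 8 rose (limma camera adjusted p = 0.805 and 0.797 as tested). In umu1 their median was −0.09 and mean 0.52, and in umu2 the median was 0.19, with the test pointing down in both. The autophagy gene atg6 fell (−0.97 ± 0.104 and −0.71 ± 0.125), though it was positive with total counts alone. MADS-box genes rose in 4 and fell in 2 of 10 in umu1 and rose in 3 and fell in 2 of 7 in umu2 (limma camera adjusted p = 0.524 and 0.999), with a umu2 median of 0.58 while the test pointed down. The umu1 set passed upward without umu1 mutant 3 (limma camera adjusted p = 0.0201, over a range of 0.0201 to 0.857), and with total counts alone it pointed down (0.600). The gene MADS5 had 5.15 ± 0.631 and 3.78 ± 1.06, and its umu2 call was lost without umu2 mutant 4 (1.79) or normal 1 (3.43) or 4 (3.61).

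SR splicing factor genes rose in 1 and fell in 3 of 13 in umu1 and rose in 1 and fell in 2 of 13 in umu2, the same adjusted over the list alone, whereas with total counts alone 13 and 11 rose (limma camera adjusted p = 0.524 and 0.658 as tested). SCL30 (GRMZM2G065066) fell by 0.54 and 0.67. Major spliceosome genes rose in 2 of 4 in umu1 and 2 of 2 in umu2, the same adjusted over the list alone. The gene smu2 had 0.49 ± 0.119 and 0.55 ± 0.138. For the minor spliceosome, both genes named Rgh3 were tested, and neither passed in either allele (edgeR's quasi-likelihood test, 0 of 2 also at an unadjusted p under 0.05). GRMZM2G128228 had 0.35 ± 0.177 and 0.07 ± 0.146, and GRMZM5G849788 had 0.06 ± 0.201 and −0.12 ± 0.208. RGH3 is the maize relative of a human splicing factor subunit that acts on minor introns. Counts for the cell wall, cell death and MADS-box lists were also the same adjusted over the list alone.

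The mutant effect differed between the alleles in 5 of 17688 models (interaction term of edgeR's quasi-likelihood test, Benjamini-Hochberg), and 1229 passed at an unadjusted p under 0.05. None has a name in the table used, and allele is also lane. GRMZM2G104768_T01 had a log2 fold change of 6.08 in umu1 and 1.87 in umu2, a difference of 4.22 ± 0.661 (SE). It was near the floor in umu1 normal siblings, at 0.122 ± 0.0519 CPM. GRMZM2G162486_T01 had 0.59 and 2.73, a difference of −2.12 ± 0.279 (SE). GRMZM2G123986_T01 fell in umu1 (−1.70) and rose in umu2 (1.74), a difference of −3.40 ± 0.548. GRMZM2G083195_T02 was at 3.86 ± 0.941 CPM in umu1 mutants against 0.0751 ± 0.0501 in normal siblings and at 3.63 ± 1.13 against 1.55 ± 0.483 in umu2. The remaining model, AC233893.1_FGT001, had 1.38 and 4.09, a difference of −2.68 ± 0.432. The call of GRMZM2G083195_T02 was lost without umu1 mutant 1 or umu1 normal 2. That of GRMZM2G104768_T01 was lost without umu1 mutant 1 or 3 or normal 1, 2 or 3, or umu2 mutant 4 or normal 1 or 4. GRMZM2G123986_T01 and AC233893.1_FGT001 lost theirs without umu1 mutant 1, 2 or 3, umu1 normal 2, umu2 mutant 4 or umu2 normal 2, 3 or 4. The former also lost it without umu2 mutant 2 and the latter without umu1 normal 3. A replicate block gave 10 models, DESeq2 55, and no low-count filter 144. The count was 1 without umu1 mutant 1 or umu1 normal 2, 2 without umu1 mutant 3, umu2 mutant 4 or umu2 normal 4, 3 without umu1 mutant 2, umu1 normal 3 or umu2 normal 2, and 8 without umu1 mutant 4 or umu1 normal 4.

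The median share of intron reads was higher in umu2 mutants, a difference that did not pass in umu1, while sums over all introns lay the other way. The median share of intron reads among intron and spanning reads was 15.6% ± 4.28 in umu1 mutants against 9.54% ± 0.444 in normal siblings (SD, n = 4; exact two-sided permutation p = 0.0857). In umu2 it was 18.0% ± 4.6 against 10.7% ± 1.18 (exact two-sided permutation p = 0.0286). Summed over introns, umu1 mutants had 41.1 ± 11.8 intron reads per 100 spanning reads against 57.0 ± 1.46 (exact two-sided permutation p = 0.0286). The umu2 mutants had 50.9 ± 8.95 against 61.3 ± 0.628 (n = 4; exact two-sided permutation p = 0.0857). Abundant transcripts weigh most in the sums. The medians count introns with few reads as fully as others and so can depend on depth. Normal libraries were shallower. Spanning reads were 5.05 to 5.94 M in umu1 normal siblings against 8.66 to 19.0 M in mutants, and 4.01 to 6.54 M against 7.19 to 8.82 M in umu2. The medians were not compared at equal depth, so an effect of depth on them stays open. The passing differences were lost on leaving out any 1 normal library of that allele. Differences in share were then 6.98 to 7.81 percentage points in umu2, against 7.22 with all libraries. In intron reads per 100 spanning reads they were −15.5 to −16.4 in umu1, against −15.9. Without umu1 mutant 2, which had 19.0 M spanning reads where the other umu1 mutants had 8.66 to 9.64 M, the umu1 difference in share passed at 8.0. Its intron reads, 4.58 M, lay within the 3.93 to 4.94 M of the others. Why its spanning reads were higher was not tested, and whether they were counted in the same way is uncertain, as are the umu1 values that rest on them. Without umu2 mutant 2 the umu2 difference in intron reads per 100 spanning reads passed at −13.9.

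In umu1, 3601 of 68905 tested introns gained and 231 lost intron reads relative to spanning reads (edgeR's quasi-likelihood test, Benjamini-Hochberg). On chromosome 2 the intron at 21484002 to 21484200 (minus strand) held 376 intron and 24 spanning reads over 4 umu1 mutants against 3 and 55 over 4 normal siblings. On chromosome 8 the intron at 62832589 to 62832690 (minus strand) lost intron reads, with 170 and 34 against 359 and 5, a log2 change of the ratio of −4.10 ± 0.778 (SE). The total of 3832 was 8664 without umu1 mutant 2 and 2105, 2343 and 2361 without umu1 mutant 1, 3 and 4, and 2505, 2412, 2130 and 2211 without umu1 normal 1, 2, 3 and 4. Centring each library on its own median gave 4551 introns, 3057 higher and 1494 lower, and intron reads alone, not set against spanning reads, gave 17171, 75.4% of them higher.

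In umu2, 2012 of 66251 tested introns gained and 76 lost intron reads relative to spanning reads (edgeR's quasi-likelihood test, Benjamini-Hochberg). The same chromosome 2 intron held 279 intron and 77 spanning reads in umu2 mutants against 9 and 61, a log2 change of 4.59 ± 0.936, and the chromosome 8 intron 230 and 89 against 822 and 3. The total of 2088 was 4751 with a replicate block. It was 769, 5650 and 348 without umu2 mutant 2, 3 and 4, and 697, 961, 930 and 526 without umu2 normal 1, 2, 3 and 4. Centring gave 1123 higher and 365 lower, a minimum of 10 reads over both kinds 3197, and intron reads alone 7731, 73.1% of them higher.

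Both alleles raised 1114 introns in common, 113 being expected of independent lists among 61388 introns tested in both (Fisher's exact test, odds ratio 30.4), and lowered 48, where 0.252 are expected (odds ratio 686, p = 7.8e-102). Introns are not independent replicates, so this Fisher's test does not measure the spread between pools. No intron was called in opposite directions (edgeR's quasi-likelihood test in each allele). The raised introns had a median mean log2 change of 2.44, 841 of them at least 4-fold and 119 at least 16-fold. With the 43 that have a group at 0 set to their bounds, the median was 2.42, with 838 and 84. The shared total of 1162 was 2063 with a replicate block (1150 of the 1162 among them), 983 with centring (756 higher and 227 lower, 796 among the 1162) and 5838 with intron reads alone, 73.6% of them higher. Without umu1 mutant 2 and umu2 mutant 2 together it was 652, of which 554 were among the 1162. It was 559, 2088 and 288 without umu2 mutant 2, 3 and 4, and 515, 629, 633 and 398 without umu2 normal 1, 2, 3 and 4.

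The most raised introns in both alleles, besides that on chromosome 2, lay on chromosomes 3, 6 and 5, in coordinates of the files, whose build is uncertain. The intron at 157740916 to 157741301 on chromosome 3 (plus strand) held 277 intron and 88 spanning reads in umu1 mutants against 3 and 78, and 163 and 47 in umu2 mutants against 0 and 58, at least 67.1-fold higher. The intron at 155982509 to 155982580 on chromosome 6 (plus strand) held 55 and 384 against 0 and 248 in umu1, at least 11.8-fold higher, and 92 and 320 against 0 and 296 in umu2, at least 28.4-fold higher. The intron at 164346481 to 164346547 on chromosome 5 (plus strand) held 41 and 93 against 0 and 47, at least 6.91-fold higher, and 44 and 69 against 0 and 74, at least 15.7-fold higher. Its umu2 call was lost without umu2 mutant 4 (at least 12.3-fold higher, adjusted p = 0.0687) or umu2 normal 2 (at least 8.93-fold higher, adjusted p = 0.0599; edgeR's quasi-likelihood test).

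The most lowered introns, besides that on chromosome 8, lay on chromosomes 1, 10 and 7. The intron at 197078170 to 197078272 on chromosome 1 (plus strand) held 23 intron and 102 spanning reads in umu1 mutants against 6 and 0, at least 8.87-fold lower, and 56 and 252 in umu2 mutants against 27 and 3, and intron reads alone were not lower. The intron at 142923513 to 142924097 on chromosome 10 (plus strand) held 35 and 43 against 38 and 1 in umu1 and 67 and 38 against 71 and 1 in umu2. The intron at 1365342 to 1366628 on chromosome 7 (minus strand) held 1115 and 12 against 1095 and 0, at least 3.93-fold lower, and 492 and 14 against 490 and 0, at least 4.65-fold lower. The chromosome 1 call was lost in umu1 without mutant 1 (at least 7.3-fold lower) or normal 2 or 3 (at least 5.91-fold in each). That of chromosome 10 was lost in umu1 without normal 2 (35 and 43 against 16 and 1), and in umu2 without mutant 4 (57 and 26 against 71 and 1) or normal 1, 2 or 4 (67 and 38 against 55, 46 or 53 intron reads and 1). That of chromosome 7 was lost in umu2 without mutant 4 (at least 4.36-fold lower) or normal 1, 2 or 4 (at least 3.33, 3.21 and 3.49-fold). Without umu1 mutant 1 or 2 or umu2 mutant 3 it had under 10 spanning reads and was not tested.

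**Figure D4:**
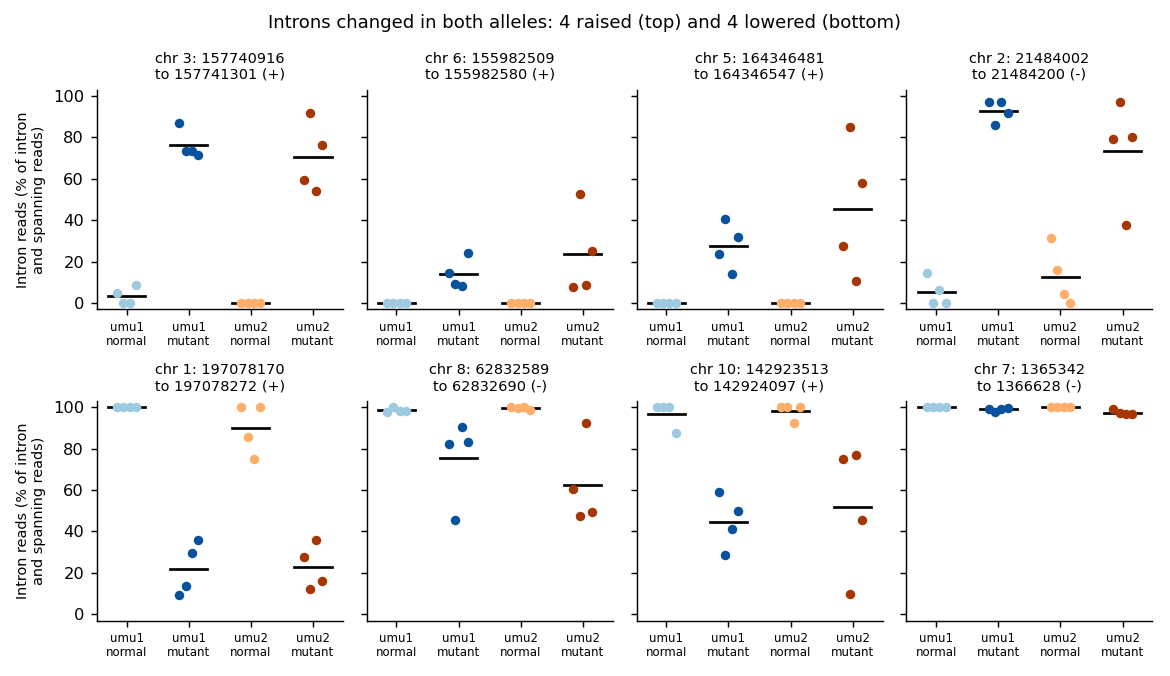
Intron reads as a percent of intron and spanning reads (y axis) in each of the 16 libraries for the 4 introns most raised (top) and the 4 most lowered (bottom) in both alleles, with a point per library and a line at the group mean. The group means of the 4 raised introns are lower in normal siblings than in mutants of both alleles, and those of the 4 lowered introns are higher.

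Introns next to raised ones, across an exon of at most 1000 bases and at least as long, rose less. Of introns raised in umu1, 1181 had such a neighbour, raised or not, and in umu2, whose libraries played no part in the choice, their median log2 change was 1.89 and that of the neighbours 1.1, against 0.58 for all tested introns. The excess over the neighbours had a median of 0.71 (quartiles −0.014 and 1.67). For 765 introns raised in umu2 and measured in umu1 the medians were 1.92 and 0.95, with a median excess of 0.93 (quartiles 0.13 and 1.93).

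For umu1, 9134 of 23229 models with an adjusted p passed 0.05 in the authors' deposited tables, and for umu2 5849 of 20413. Their fold changes have the opposite sign in all models called both there and here, so they are normal over mutant: 5439 of the 9134 and 3431 of the 5849 are negative in the authors' deposited tables, that is, higher in mutants. Of the 7841 and 4575 models called here, 7602 and 4484 are also called in the authors' deposited tables.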

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

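The tests of explanations and the counts over other splits of the libraries given here were chosen after the results they bear on had been seen.

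Zein transcripts, the main storage protein transcripts, took less of the mutant libraries in both alleles. Whether reads lost to the class that fits several models make up the whole of it cannot be told over all zeins. Zeins with a single model cannot lose reads to a second model of their gene. Of these, 20 of 20 fell in umu1 and 19 of 20 in umu2, relative to the bulk of transcripts. For these zeins that argues against such sharing as the whole cause, while overlap with models of other genes stays open. Zeins held 6.17% of counted reads in umu1 mutants and 11.3% in umu2 mutants, against 26.4% and 26.9% in normal siblings. Adding the whole rise of that class brings the mutants to 19.1% and 21.2%. That is no upper limit, since how much of that class is zein reads is unknown in both genotypes. A fall of zein transcripts and a rise of the other transcripts cannot be told apart: zeins had a median log2 fold change of −1.32 in umu1 and −0.64 in umu2 with total counts alone, but each count is a share of its library. A lag in kernel development, or a change in the mix of endosperm cell types, was not tested and stays open.

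Introns with more intron reads per spanning read were shared by both alleles. Whether DNA or unprocessed transcripts carried over make up the whole of it cannot be told. Introns raised in umu1 exceeded all neighbours at least as long by a median log2 of 0.71 when measured in umu2 (quartiles −0.014 and 1.67, 1181 introns). The excess was 0.93 the other way round (765 introns). These neighbours were chosen by length alone, though, and added reads raise a ratio most where it is lowest in normal siblings. The neighbours rose by 1.1 and 0.95, above the 0.58 and 0.44 of all tested introns, so carry-over stays open. The share of reads outside models was higher in mutants of both alleles. A smaller zein share raises the shares of all other reads, so this rise does not tell whether reads were carried over. Reads outside models were highest in umu2 mutant 2 (13.0%), the library with the highest median intron share (23.9%). Introns raised in both alleles were also long, with a median of 720 bases against 140 for neighbours not raised. A shift of whole libraries does not account for all of the set, since 796 of 1162 introns were called again with each library centred, but the shared calls went from 1114 higher and 48 lower to 756 and 227. The libraries umu1 mutant 2 and umu2 mutant 2 do not make up the whole of it either. Without both, 652 introns were called, 554 of them among the 1162, where other splits of the libraries left are bounded by 473. Without umu2 mutant 2 alone the count was 559 and without umu1 mutant 2 alone 1555. A candidate explanation for part of the set is a loss of splicing at these introns in rbm48 mutants, and whether they are minor introns was not analysed here. A difference in decay of unspliced transcripts between genotypes was not tested and stays open.

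More models were called in umu1 than in umu2, by a ratio of 1.71. Depth is argued against, since thinning all libraries to 8.82 M effective reads gave 6945 and 4053 calls, again a ratio of 1.71. Over the 13309 models tested in both alleles a likelihood ratio test in edgeR gave a ratio of 1.43 (7078 and 4941) with the spread of each allele and of 1.19 (6692 and 5645) with one spread for both, so a larger spread between umu2 libraries may account for much of it. With all 16 libraries in one fit the calls were 7741 and 6143, a ratio of 1.26. The common coefficient of variation was 0.273 in umu1 and 0.301 in umu2. What remains open is a stronger effect of umu1, which cannot be told apart from its lane.

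Other splits of the libraries seldom gave as many calls as the real one. For models in umu1, 1 of 35 splits, the real one, gave 7841, and the highest other gave 1. For umu2, 1 of 35 gave 4575, the highest other 0, and for both alleles 1 of 100 gave 3924, the highest other 0 (edgeR's quasi-likelihood test). For introns, 1 of 35 gave 3832 in umu1, the highest other 62, 1 of 35 gave 2088 in umu2, the highest other 1, and 1 of 100 gave 1162 in both, the highest other bounded by 33. A share under 0.05 of all splits gave as many calls in these 6 results. That argues against a chance split only if the pairing of libraries is set aside. The counts for both alleles add little, since a split with few calls in 1 allele leaves few shared calls. For lists in umu1, 1 of 35 gave 7, the highest other 6 in 4 splits, and of the 8 splits that part every pair, too few for a share under 0.05, 1 gave 7 and the highest other 6. That count was also 6 without any 1 umu1 normal library, 5 with total counts alone or single-model genes and 0 with an estimated correlation. For lists in umu2, 10 of 35 splits gave at least the real 4, the highest other 7, so chance is not excluded, and of the 8 splits that part every pair 4 gave as many, the highest other 6, while the replicate block left 4 lists. For the allele difference, 3 of 100 splits gave at least the real 5, and the highest other gave 2900. These splits exchange libraries between alleles and so between lanes, so they do not show what chance gives, and chance is not excluded. The split with 2900 kept the umu1 mutants and set umu1 normal 2 with umu2 normal 2, 3 and 4, and another with 425 set umu1 mutants 1 to 3 and umu2 mutant 4 with all umu2 normal libraries, which points to a structure of the samples along allele and lane. Among the 8 splits of each allele that part every pair, which are too few for a share under 0.05, the highest other gave 0 models in either allele and 29 introns in umu1 and 0 in umu2.

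Single libraries stood far from the other 3 of their group in 15 of 148 groups tested. Chance gives about 1 in 20 for values that follow a normal distribution. Several of the values below lie near 0 CPM, where single reads set the spread, so no excess over chance is shown. Spanning reads were 19.0 M in umu1 mutant 2, and the median intron share was 12.5% in umu2 normal 2. LTP3 was at 0.714 CPM in umu1 normal 3 and 0.0843 in umu2 normal 1. The gene bap-3a was at 27.8 CPM in umu1 mutant 3, 0.591 in umu1 normal 1 and 22.5 in umu2 mutant 1. HAK5 was at 2.41 CPM in umu1 mutant 3, MYB112 at 2.30 in umu1 normal 4 and 0.573 in umu2 normal 4, and dhn1 at 2.60 in umu1 normal 4. NAC78 was at 3.92 CPM in umu2 mutant 3 and the z1A1_3 model GRMZM2G059620_T03 at 1576 in umu2 mutant 2. Of the models that differed between alleles, GRMZM2G083195_T02 was at 0 CPM in umu1 normal 3 and GRMZM2G104768_T01 at 0.200 in umu1 normal 4.

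The allele difference of the log2 fold change, umu1 minus umu2, was 4.40 for GRMZM2G083195_T02, 4.22 for GRMZM2G104768_T01, −2.12 for GRMZM2G162486_T01, −3.40 for GRMZM2G123986_T01 and −2.68 for AC233893.1_FGT001, and each passed the interaction test. Outside the counts of models, reads that fit several models averaged 50.8% in umu1 and 44.5% in umu2 mutants, and reads outside models 10.1% and 9.75%, each above the 6.73% and 6.81% or, for the former, the 37.9% and 34.6% of normal siblings. Reads outside models differed at exact two-sided permutation p = 0.0286 in each allele (n = 4). The umu2 call was lost without any 1 umu2 normal library. The difference was then 2.81 to 3.04 percentage points, against 2.94 with all libraries.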

How the results depend on the processing

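Alternatives chosen after the data were seen were counts summed per gene, single-model genes, leaving out zeins, centred intron ratios, leaving out umu1 mutant 2 and umu2 mutant 2, and, for lists, library values and shared introns, leaving out each library. Of counts of calls 84 stayed within 1.5 times under an alternative and 47 did not. Of named genes' values 3144 kept their side of the threshold, 88 lost and 47 gained a call, and 36 were counted as turned in sign, all with total counts alone. Some values not called in the main test turned sign and are not among the 36. Examples in umu2 are hsp1, SCL30 (GRMZM2G065298) and ESR1 (GRMZM2G315601) with total counts alone, and phb1 with RLE scaling. Of list tests 346 kept their side of the threshold, 24 lost and 7 gained a call. Some sets not called turned direction, as did the basal transfer layer in umu2 with total counts alone. Of named introns' values 182 kept direction and side of the threshold, 16 lost a call and 2 turned sign. Of allele differences 80 kept both and 29 lost a call, and of library values 120 kept both, 20 lost and 4 gained a call. The replicate block, which treats libraries as paired, gave 10 models for the allele difference, 4751 introns in umu2 and 2063 in both alleles. It ended the call of the allele difference of AC233893.1_FGT001 (−2.62), gave calls to ole17 (1.07), hsp1 (−0.78) and srp30 (0.91) in umu1 and to MEG1 and esr-6 in umu2, and changed no other call. Causes of these changes were not tested. U12-type introns and their host genes, planned with their alternatives, were not run, since no genome sequence was used here.

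Total counts alone gave 13943, 11366 and 10745 changed models in umu1, umu2 and both, and the cause was not tested. A 2-fold limit gave 5007 and 2774, and fewer by construction. The allele difference had 144 models without the low-count filter and 55 with DESeq2, and 1 to 8 on leaving out a library. Intron reads alone gave 17171 introns in umu1, 7731 in umu2 and 5838 in both, and a minimum of 10 reads over both kinds gave 3197 in umu2. Leaving out a library gave 2105 to 8664 introns in umu1, 348 to 5650 in umu2 and 288 to 2088 in both, and leaving out umu1 mutant 2 and umu2 mutant 2 gave 652. Lists past the test numbered 0 in both alleles with an estimated correlation (limma camera; 1 in each at an unadjusted p under 0.05), and 3 to 7 in umu2 on leaving out a library, 7 without umu2 mutant 2. Leaving out a library gave 6867 to 7760 changed models in umu1, 3605 to 5333 in umu2 and 3150 to 4338 in both, and 6 to 8 lists in umu1.

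With total counts alone log2 fold changes turned positive in umu1 for PYL10 (0.81), ARF11 (0.68), atg6 (0.73), atg9 (1.00), CesA-6 (0.79), pbf1 (0.091), DOF36 (0.22), o2 (0.39), der2 (0.84), hsfb (1.15), hsp1 (1.03), Hsf03 (1.17), zmm16 (1.1), phb1 (1.52), both SCL30 genes (1.17 each), SR45_2 (1.1), ss1 (0.069), sbe1 (0.66) and ae1 (0.20). In umu2 they did so for PYL6 (0.42), PYL10 (0.40), ARF11 (0.46), atg6 (0.73), atg9 (1.17), CesA-6 (0.62), pbf1 (0.078), der2 (0.83), Hsf01 (0.087), hsfb (0.85), zmm16 (0.59), Rgh3 (GRMZM5G849788, 1.29), SCL30 (GRMZM2G065066, 0.76), SR45_2 (0.95), sbe1 (0.37) and ae1 (0.22). The genes hsp1, SCL30 (GRMZM2G065298) and ESR1 (GRMZM2G315601), not called in umu2 in the main test, also turned positive there. With intron reads alone the change of the intron at 197078170 on chromosome 1 was 0.68 in umu1 and 0.063 in umu2.

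With the depth, spread and 4 libraries per group here, 25 to 32% of simulated 2-fold changes were recovered in models, and no simulation varied depth alone. Thinning all libraries to 8.82 M effective reads gave 6945 and 4053 changed models in umu1 and umu2. A model or intron not called is not shown to be unchanged.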

Other observations

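Tests named in this part use the thresholds set in advance, and the comparison of intron lengths was chosen after the data were seen. Further members of the gene lists moved in both alleles (log2 fold changes in umu1 and umu2, SE). The expansin genes expB2 (4.18 ± 0.577 and 2.31 ± 0.662) and expA4 (1.75 ± 0.460 and 1.69 ± 0.586) and the legumain-type protease gene see2b (2.54 ± 0.369 and 1.56 ± 0.490) rose, as did the ribonucleotide reductase gene RNRS3 (2.79 ± 0.362 and 1.49 ± 0.372), the ribosomal gene RPS21 (1.98 ± 0.229 and 1.20 ± 0.238), the protein disulfide isomerase gene pdi8 (0.84 ± 0.167 and 1.15 ± 0.192) and the MADS-box genes zmm27 (5.29 ± 0.898 and 3.06 ± 0.872) and MADS37 (4.84 ± 0.727 and 2.52 ± 0.824). Each umu2 call of expB2, expA4, see2b, zmm27 and MADS37 was lost without umu2 normal 4 (2.11, 1.37, 1.61, 2.87 and 2.51). The expB2 call was also lost without umu2 mutant 2 (1.91), that of expA4 without umu2 mutant 1 (1.5), 2 (1.43) or 4 (1.82) or normal 2 (1.66) or 3 (1.47), and that of see2b without umu2 mutant 4 (0.81) or normal 2 (1.44) or 3 (1.38). The zmm27 and MADS37 calls were also lost without umu2 mutant 4 (1.45 and 1.14), normal 1 (2.92 and 2.19) or normal 3 (2.98 and 2.31). The heat shock gene hsfb (−0.56 ± 0.156 and −0.59 ± 0.170) and zmm16 (−0.59 ± 0.191 and −0.80 ± 0.248) fell, though both were positive with total counts alone. The zmm16 call was lost without umu1 mutant 1 (−0.51) or 3 (−0.49), umu1 normal 2 (−0.57) or 3 (−0.52), or umu2 normal 1 (−0.74) or 2 (−0.82), and the hsfb call in umu2 without umu2 normal 2 (−0.57). The splicing factor genes srp30 (1.46 ± 0.293) and 70 K (1.12 ± 0.270) and the prohibitin gene phb3 (3.16 ± 0.699) rose in umu2 and did not pass in umu1 (0.81, 0.47 and 0.91; srp30 did with a replicate block, 0.91), and none of the 3 passed the test of the allele difference.

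Introns raised in both alleles were long. Their median length was 720 bases, against 140 for tested neighbours that were not raised and 224 for all other tested introns. The lengths are a description, and no test was run on them.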
